A study of Mus musculus with 18 samples.

How the data were processed

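RNA of TA muscle was sequenced in 18 libraries of 9 groups, 2 libraries per group. Per the labels, total RNA was extracted with Trizol from snap-frozen muscle, and poly(A) libraries were made with a directional kit and sequenced as pairs on a NovaSeq instrument. The authors demultiplexed the reads with bcl2fastq (2.20) and quantified them with Salmon on mouse transcripts of build mm10. The version of Salmon, its strand setting and the release of the transcripts are not given in the sources used here. Each deposited library file held, for 140825 transcripts, the effective length, the TPM (transcripts scaled within the library by Salmon) and the estimated counts of fragments, which the authors had not normalised. The authors also deposited 5 tables made with DESeq2 from their gene-level data, with the log2 fold change and its standard error, the p-value and the adjusted p-value of each of 24569 genes.

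Transcripts were matched by identifier to the GENCODE M21 annotation of mm10. Of the transcripts, 139881 matched and 944 did not, and the unmatched held 0.416 to 0.693% of the fragments of a library. Estimated counts were summed per gene and rounded. The total was 22546541 to 36673780 fragments per library, and 29433 genes had a count. TPM and effective length were used only in an alternative with length-scaled counts.

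Genes were filtered with filterByExpr of edgeR (4.0.16), which kept 16089, and libraries were scaled by TMM. CPM are counts scaled to the normalised library size. 1 model of 9 groups was fitted with edgeR's quasi-likelihood method (9 residual degrees of freedom, prior degrees of freedom 5.1, common dispersion 0.0539). Tested were the 5 tumour groups against their controls, KPC against KPCML1, and the differences among the 5 models jointly and in 10 pairs. P values were adjusted over all tested genes by Benjamini and Hochberg, and genes under 0.05 were called. The labels call the libraries of a group biological replicates, and 4 libraries fitted alone leave 2 residual degrees of freedom.

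Before the data were examined, the groups, the model, 39 gene lists, the alternatives and the rule on named genes were fixed. The lists cover protein breakdown, signalling, contractile and metabolic functions, stress responses and markers of cell types. All but the list of sex-linked genes, 38 lists, were tested. They were tested with camera of limma (3.58.1), with the preset correlation between genes of 0.01 on log2 CPM with a prior count of 2, and again with a correlation estimated from the data. Differences of lists between models were tested in 380 comparisons. Named were 20 panel genes, the 6 largest increases and 6 largest decreases of each comparison, up to 4 members of smallest p of each list described, 10 genes common to all models, and the 10 genes of smallest p in the test among models. The largest changes needed a mean CPM of at least 5 in the higher group and both tumour libraries on the same side of both controls, and predicted names, pseudogenes and immunoglobulin or T-cell receptor segments were left out. A few results that this rule would name are not reported here.

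Against a group with 0 counts the fold is a lower bound taken at 3 counts over the group. With 1 to 3 counts in a group the ratio is given with its exact 95% interval. These floors and intervals cover counting error only. Reads shared between near-identical genes, such as Serpina3m and Serpina3n or Myh1, Myh2 and Myh4, were divided by Salmon, so values of single members of such families carry that uncertainty.

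The alternatives were size factors by relative log expression, DESeq2 (1.42.0), no filter on low counts, a fold threshold of 2, length-scaled counts, replicate number as a block, a fit to the libraries of each experiment alone, fry and the estimated correlation for lists, and leaving out each library in turn. With 1 library left out its partner is alone in its group and is assumed to vary like the other groups. A crossed block in the KPP experiment was added after the data were seen. In simulated data 200 of 16089 genes changed between LLC groups. Of 100 changed 2-fold 48% were called, of 100 changed 4-fold 97%, and 4 unchanged genes. A list shifted by -0.5 was called with both correlations, and 0 others with the preset. Genes were drawn independently, so correlated lists were not tested. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.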

Results

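The transcriptome of the tibialis anterior (TA) muscle was measured by poly(A) RNA sequencing in 18 libraries from mice with 5 models of cancer cachexia and their controls. The libraries fell into 9 groups of 2, each library labelled a biological replicate. LLC is a mouse lung carcinoma line injected into muscle, with PBS-injected controls. C26 is a mouse colon carcinoma line injected under the skin of CD2F1 mice, with PBS-injected controls. KPC and KPCML1 are tumour lines placed orthotopically (50000 and 1000 cells), and both were compared with the same 2 Matrigel-injected controls. KPP is a genetic tumour model induced with tamoxifen, compared with mice of that model without tumour. All mice except the C26 experiment were C57BL/6, and the muscles were taken at endpoint.

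Of 29433 genes with a count, 16089 passed the filter on low counts and were tested. The correlation across genes between the 2 libraries of a group ran from 0.959 in the KPP controls to 0.983, where genes are not independent replicates. The first principal component held 31.2% of the variance and had every control library on its negative side and every tumour library on its positive side. The second, with 19.6%, set the 4 C26 libraries apart from the other 14. Mitochondrially encoded transcripts made up 5.94 to 22.4% of the fragments, and in each experiment every tumour library lay below its controls. Xist stayed at or below 0.35 CPM and Ddx3y at or above 44.09 CPM in all libraries. Below, values in parentheses after a gene are log2 fold changes, tumour minus control, ± the standard error of the fit (n = 2 libraries per group), and adjusted p values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

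**Figure D1:**
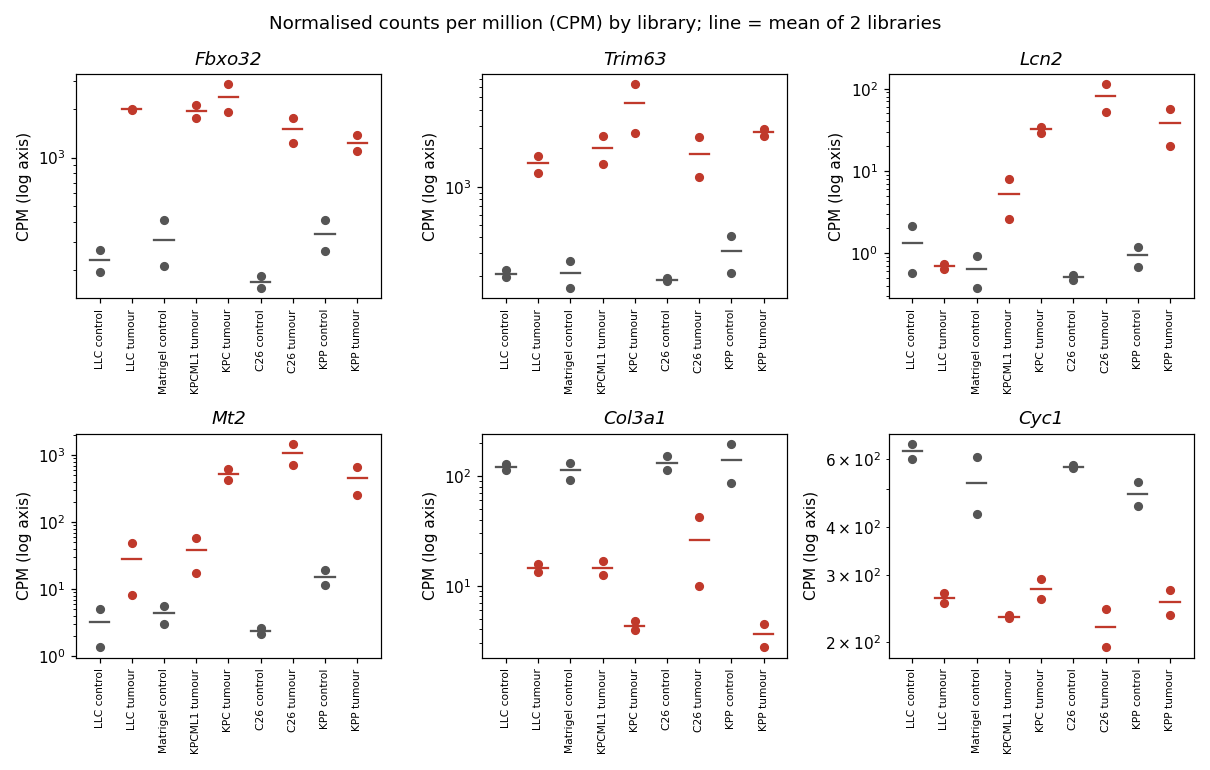
Normalised CPM (log axis) of 6 genes in each library (points) with the mean of each group of 2 libraries (lines), controls in grey and tumour groups in red. In every model Fbxo32 and Trim63 lay above the controls in both tumour libraries, and Col3a1 and Cyc1 lay below them.

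The LLC comparison asked how muscle of mice with LLC tumours differed from that of PBS-injected mice. Called higher were 15 of 33 proteasome genes and 7 of 26 ubiquitin ligase genes, and called lower 40 of 51 oxidative phosphorylation, 14 of 29 glycolysis and 16 of 39 collagen and matrix genes. These lists passed camera with the preset correlation but not with an estimated correlation (adjusted p 0.24 to 0.39). Fbxo32 (atrogin-1), a muscle ubiquitin ligase on chromosome 15 (58175879 to 58214932, build mm10), rose from 230 ± 50.4 to 1990 ± 29.2 CPM (SD, n = 2), a log2 fold change of 3.12 ± 0.35. Trim63 (MuRF1), a ubiquitin ligase of the sarcomere on chromosome 4 (134315120 to 134329629), rose from 209 ± 19.5 to 1520 ± 329 CPM (2.86 ± 0.47). The chemokine gene Cxcl10 rose from 0.0825 ± 0.0636 to 8.13 ± 0.697 CPM (6.58 ± 1.12), and the NF-kB subunit genes Nfkb2 (3.86 ± 0.29) and Relb (2.95 ± 0.29) rose as well.

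Other large increases were in Elf3, an epithelial transcription factor (5.72 ± 0.92), the potassium channel gene Kcnk5 (4.84 ± 0.74), Depp1, a target of FoxO factors (4.64 ± 0.50), and the carboxylesterase gene Ces2c (4.64 ± 0.72). Ggt6 had 2 counts over both controls, and its ratio of tumour to control was 133 (95% counting interval 36.5 to 1100). Large decreases were in the peptide transporter gene Slc15a2 (-5.80 ± 1.46), Col9a1 (-5.00 ± 0.50), the antisense RNA gene Irx3os (-4.85 ± 0.58), Ostn, which encodes the secreted peptide osteocrin (-4.28 ± 0.61), and Nmrk2, a muscle nicotinamide riboside kinase (-4.08 ± 0.54). Except for Slc15a2, which lost its call in each case (adjusted p 0.051 to 0.167), these genes were called with each of the 4 libraries left out in turn. The strand setting of the quantification is not given, so assignment to antisense genes is uncertain.

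Of 33 proteasome subunit genes, 15 rose (24 adjusted over the list alone), among them Psmd2 (1.42 ± 0.22); adjusted p = 5.2e-10 by camera, and adjusted p = 0.39 with an estimated correlation. Of 26 atrophy-related ubiquitin ligase genes, 7 rose (10 higher and 1 lower adjusted over the list alone; adjusted p = 2.4e-04, adjusted p = 0.38 with an estimated correlation). In the list of glucocorticoid and FoxO targets 15 of 28 rose (19 adjusted over the list alone; adjusted p = 1.1e-09, adjusted p = 0.24 with an estimated correlation), among them Gadd45a (4.06 ± 0.37), Arrdc2 (3.35 ± 0.45) and Cebpb (2.47 ± 0.33). Of 24 NF-kB targets 11 rose (12 adjusted over the list alone; adjusted p = 5.6e-06, adjusted p = 0.23 with an estimated correlation). Antioxidant and metallothionein genes rose in 12 of 22 cases and fell in 1 (17 and 1 adjusted over the list alone), led by Srxn1 (2.32 ± 0.21), Nqo1 (2.12 ± 0.27) and Gclm (1.95 ± 0.32), which act in the oxidative stress response; this list passed both with the preset (adjusted p = 8.0e-08) and with an estimated correlation (adjusted p = 0.022). The immediate early genes Myc (3.20 ± 0.38) and Jun (1.89 ± 0.22) rose. The denervation-responsive genes Musk (2.95 ± 0.51) and Hdac4 (2.35 ± 0.32) rose in a list with 8 higher and 2 lower of 25 (8 and 3 adjusted over the list alone; adjusted p = 0.040, adjusted p = 0.47 with an estimated correlation). That list's adjusted p was 0.110 without LLC_control replicate 2 and 0.0906 without LLC_tumor replicate 2.

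Of 51 oxidative phosphorylation genes 40 fell (48 adjusted over the list alone; adjusted p = 1.4e-21, adjusted p = 0.38 with an estimated correlation), among them Cyc1 (-1.27 ± 0.19) and Sdhd (-1.31 ± 0.20). Of 29 glycolysis and glycogen genes 14 fell (18 lower and 2 higher adjusted over the list alone; adjusted p = 2.0e-08, adjusted p = 0.24 with an estimated correlation), among them Tpi1 (-2.51 ± 0.27) and Eno3 (-2.95 ± 0.35). Collagen and matrix genes fell in 16 of 39 cases and rose in 1 (23 and 1 adjusted over the list alone; adjusted p = 2.6e-07, adjusted p = 0.39 with an estimated correlation), among them Fbn1 (-2.27 ± 0.42) and Postn (-2.97 ± 0.56). Tendon markers fell in 3 of 12 cases (4 adjusted over the list alone; median -1.97; adjusted p = 0.0034, adjusted p = 0.41 with an estimated correlation). Of these, 1 was called without LLC_control replicate 2, where the list's adjusted p was 0.0746, 1 without LLC_tumor replicate 1 and 0 without LLC_tumor replicate 2. Fibro-adipogenic progenitor markers fell in 4 of 20 cases (5 adjusted over the list alone; median -0.85; adjusted p = 6.6e-04, adjusted p = 0.39 with an estimated correlation), and 1 was called without either LLC_control replicate or without LLC_tumor replicate 2. Of 18 fast myofibre genes 6 fell (8 adjusted over the list alone), including Mylpf (-1.44 ± 0.24), with adjusted p = 1.8e-04, and adjusted p = 0.39 with an estimated correlation. Myh4, the main fast myosin gene, had a value of 0.34 ± 0.42 that did not pass. Beside these groups, erythroid markers had a median of 2.48 (6 of 10 higher and 1 lower, 8 and 1 adjusted over the list alone; adjusted p = 0.0027, adjusted p = 0.41 with an estimated correlation). Neutrophil markers had a median of 2.05 (4 of 13 higher, 6 adjusted over the list alone; adjusted p = 6.6e-04, adjusted p = 0.24 with an estimated correlation) and adipocyte markers of 2.01 (2 of 13 higher, 5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0034, adjusted p = 0.38 with an estimated correlation). Without LLC_control replicate 1, 0 erythroid, 2 neutrophil and 0 adipocyte markers were called higher. Without LLC_control replicate 2 these were 1, 0 and 0, without LLC_tumor replicate 1 they were 6, 1 and 2, and without LLC_tumor replicate 2 they were 0, 2 and 0. The number of oxidative phosphorylation genes called lower was 5 without LLC_control replicate 1, 6 without LLC_tumor replicate 2, 21 without LLC_tumor replicate 1 and 29 without LLC_control replicate 2.

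In this comparison 2193 of 16089 genes passed the test, 1189 higher and 1004 lower, and 20 of 38 lists passed camera with the preset correlation against 1 with an estimated correlation. More genes were lower than higher with a fold threshold of 2 (623 higher and 641 lower), without LLC_control replicate 1 (226 and 276) and without LLC_control replicate 2 (441 and 490). The count of genes was 502 without LLC_control replicate 1, 931 without LLC_control replicate 2, 1208 without LLC_tumor replicate 1 and 590 without LLC_tumor replicate 2. With replicate number as a block it was 1329, and with the 4 libraries of this experiment alone it was 3935. By fry, the lists of neuromuscular genes (adjusted p = 0.059) and of fibro-adipogenic (0.052), erythroid (0.052) and tendon markers (0.085) did not pass. Without LLC_control replicate 1, 1 proteasome gene, 3 ubiquitin ligases, 6 glucocorticoid and FoxO targets, 5 NF-kB targets and 5 antioxidant genes were called higher, and 5 collagen genes and 9 glycolysis genes lower. Without LLC_control replicate 2, 6 proteasome genes, 5 NF-kB targets and 6 antioxidant genes were called higher, and 4 collagen genes lower. Without LLC_tumor replicate 1, 8 proteasome genes were called higher, and 4 collagen genes lower. Without LLC_tumor replicate 2, 5 proteasome genes, 4 ubiquitin ligases, 7 glucocorticoid and FoxO targets, 5 NF-kB targets and 6 antioxidant genes were called higher, and 3 collagen genes and 9 glycolysis genes lower.

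The KPCML1 comparison asked how muscle differed between mice given 1000 KPCML1 cells and mice given Matrigel. Called higher were 18 of 28 glucocorticoid and FoxO targets, 10 of 23 STAT3 and acute phase genes and 8 of 13 neutrophil markers, and called lower 11 of 39 collagen and matrix genes (0 without KPCML1_tumor replicate 2). With an estimated correlation the neutrophil list passed (adjusted p = 0.029) and the other 3 did not (adjusted p 0.26 to 0.50). Fbxo32 rose from 309 ± 139 to 1940 ± 265 CPM (SD, n = 2; 2.65 ± 0.34) and Trim63 from 211 ± 70.2 to 2010 ± 699 CPM (3.25 ± 0.47). Cebpd, a transcription factor of the acute phase, rose by 4.05 ± 0.42 and Pdk4, a pyruvate dehydrogenase kinase gene, by 3.61 ± 0.54. S100a9, a calcium-binding protein abundant in neutrophils, rose from 0.395 ± 0.221 to 9.83 ± 5.02 CPM (4.61 ± 0.48).

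The other large increases, with erythroid genes left aside, were in Tmem252 (4.45 ± 0.31), the acyl-CoA thioesterase gene Acot1 (4.37 ± 0.78), S100a8 (4.35 ± 0.98), the lipoprotein lipase inhibitor gene Angptl4 (4.32 ± 0.87) and Doc2b (4.26 ± 1.14). The largest decreases were in the antisense genes Irx3os (-5.03 ± 0.57) and Foxo6os (-4.69 ± 0.61), Nmrk2 (-4.46 ± 0.56), Nrep (-4.26 ± 0.55), the fibrillar collagen gene Col1a1 (-3.95 ± 0.79) and the cartilage and tendon gene Chad (-3.85 ± 1.07). Of these 12 genes, 6 kept a call with each of the 4 libraries left out in turn. Calls ended in Acot1 without Matrigel_control replicate 2 or KPCML1_tumor replicate 2 (adjusted p 0.0596 to 0.0759), in S100a8 (0.0849 to 0.164) and Angptl4 (0.0607 to 0.0867) without either of these or Matrigel_control replicate 1, in Col1a1 (0.0533 to 0.128) and Chad (0.0517 to 0.492) without Matrigel_control replicate 1 or either KPCML1_tumor replicate, and in Doc2b without any of the 4 (0.0506 to 0.198).

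Of 28 glucocorticoid and FoxO targets 18 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 2.2e-11, adjusted p = 0.26 with an estimated correlation), among them Sesn1 (3.91 ± 0.58), Eif4ebp1 (2.54 ± 0.34) and Pik3r1 (2.47 ± 0.37). STAT3 and acute phase genes rose in 10 of 23 cases (14 adjusted over the list alone; adjusted p = 2.2e-08, adjusted p = 0.28 with an estimated correlation), among them the interleukin-6 receptor gene Il6ra (3.39 ± 0.51) and Il4ra (1.62 ± 0.27). Neutrophil markers rose in 8 of 13 cases (11 adjusted over the list alone), including S100a9, and passed with the preset (adjusted p = 3.0e-11) and with an estimated correlation (adjusted p = 0.029). Macrophage markers rose in 6 of 20 cases (10 adjusted over the list alone; adjusted p = 7.9e-07, adjusted p = 0.41 with an estimated correlation), and erythroid markers in 8 of 10 (8 adjusted over the list alone; median 3.74; adjusted p = 2.9e-06, adjusted p = 0.41 with an estimated correlation), among them Slc4a1 (5.60 ± 0.89). Cytosolic ribosomal protein genes rose in 16 of 59 cases (49 adjusted over the list alone; adjusted p = 3.1e-16, adjusted p = 0.41 with an estimated correlation). Adipocyte markers rose in 7 of 13 cases (7 higher and 1 lower adjusted over the list alone; median 1.80; adjusted p = 1.2e-04, adjusted p = 0.28 with an estimated correlation). Of these, 0 were called without either Matrigel control, 3 without KPCML1_tumor replicate 1 and 1 without KPCML1_tumor replicate 2.

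Collagen and matrix genes fell in 11 of 39 cases and rose in 1 (13 and 1 adjusted over the list alone; adjusted p = 6.4e-05, adjusted p = 0.50 with an estimated correlation). Tendon markers fell in 3 of 12 cases (6 adjusted over the list alone; median -2.31; adjusted p = 3.9e-05, adjusted p = 0.41 with an estimated correlation), and 0 were called without Matrigel_control replicate 1 or KPCML1_tumor replicate 2. Oxidative phosphorylation genes had a median of -0.48, with 7 of 51 lower (13 adjusted over the list alone; adjusted p = 3.9e-09, adjusted p = 0.50 with an estimated correlation), and mitochondrially encoded transcripts a median of -1.08. The polyamine oxidase gene Smox (-2.57 ± 0.34) and the clock output genes Dbp (-2.86 ± 0.32) and Hlf (-1.59 ± 0.20) fell. Proteasome genes rose in 4 of 33 cases (9 adjusted over the list alone; adjusted p = 4.9e-06, adjusted p = 0.53 with an estimated correlation). The list's adjusted p was 0.0642 without KPCML1_tumor replicate 2. By edgeR 0 of the ribosomal protein genes were called without KPCML1_tumor replicate 2 or either Matrigel control, and 20 without KPCML1_tumor replicate 1.

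In total 1373 genes passed, 668 higher and 705 lower, and 21 lists passed camera with the preset correlation against 1 with an estimated correlation. More genes were higher than lower with no filter on low counts (1156 higher and 1088 lower), without KPCML1_tumor replicate 1 (487 and 402) and without KPCML1_tumor replicate 2 (78 and 62). The count of genes was 456 without Matrigel_control replicate 1, 211 without Matrigel_control replicate 2, 889 without KPCML1_tumor replicate 1 and 140 without KPCML1_tumor replicate 2. With the replicate block it was 690, with a fold threshold of 2 it was 850, and with no filter on low counts 2244. By fry, collagen (adjusted p = 0.13), oxidative phosphorylation (0.1), proteasome (0.12) and mitochondrially encoded (0.054) lists did not pass. Without Matrigel_control replicate 1, 8 glucocorticoid and FoxO targets, 4 STAT3 genes, 4 neutrophil markers and 1 erythroid marker were called higher, and 1 collagen gene and 3 oxidative phosphorylation genes lower. Without Matrigel_control replicate 2, 3 glucocorticoid and FoxO targets, 4 STAT3 genes, 3 neutrophil markers, 0 macrophage markers and 1 erythroid marker were called higher, and 5 collagen genes and 0 oxidative phosphorylation genes lower. Without KPCML1_tumor replicate 1, 6 STAT3 genes and 2 macrophage markers were called higher, and 2 collagen genes and 2 oxidative phosphorylation genes lower. Without KPCML1_tumor replicate 2, 5 glucocorticoid and FoxO targets, 3 STAT3 genes, 2 neutrophil markers, 0 macrophage markers and 1 erythroid marker were called higher, and 0 collagen genes and 1 oxidative phosphorylation gene lower.

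The KPC comparison asked how muscle differed between mice given 50000 KPC cells and the same Matrigel controls. Called higher were 14 of 23 STAT3 and acute phase genes and 16 of 26 ubiquitin ligase genes, and called lower 22 of 39 collagen and matrix genes and 17 of 29 interferon-response genes. These 4 lists passed camera with the preset correlation but not with an estimated correlation (adjusted p 0.25 to 0.55). Trim63 rose from 211 ± 70.2 to 4480 ± 2600 CPM (SD, n = 2; 4.41 ± 0.50) and Fbxo32 from 309 ± 139 to 2380 ± 658 CPM (2.95 ± 0.34). The metallothionein gene Mt2 on chromosome 8 (94172664 to 94173568) rose from 4.37 ± 1.89 to 527 ± 151 CPM (6.91 ± 0.98), and the cell cycle inhibitor gene Cdkn1a from 5.27 ± 1.90 to 406 ± 277 CPM (6.26 ± 0.65). Mstn (myostatin), a negative regulator of muscle mass, rose by 2.50 ± 0.33, while the satellite cell gene Pax7 fell (-2.24 ± 0.44).

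Further large increases were in BB123696 (6.77 ± 0.91), Doc2b (6.60 ± 1.18) and the keratin gene Krt14 (6.27 ± 1.96), and Retnlg, with 3 counts over both controls, had a ratio of 123 (95% counting interval 41.9 to 601). The largest decreases were in Irx3os (-6.47 ± 0.65), Col1a1 (-5.70 ± 0.88), Amd1, which encodes an enzyme of polyamine synthesis (-5.62 ± 0.49), Nrep (-5.34 ± 0.59), Chad (-5.26 ± 1.20) and Nmrk2 (-5.12 ± 0.58). Of these 12 genes, 10 were called with each of the 4 libraries left out in turn; Krt14 lost its call in each case (adjusted p 0.0529 to 0.143) and Chad without Matrigel_control replicate 1 (0.0922). The slow myosin gene Myh7 (4.69 ± 1.45) was called with all libraries and lost its call without Matrigel_control replicate 1, Matrigel_control replicate 2 or KPC_tumor replicate 1 (adjusted p 0.121 to 0.699).

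Glucocorticoid and FoxO targets rose in 25 of 28 cases and fell in 1 (26 and 1 adjusted over the list alone; adjusted p = 9.8e-14, adjusted p = 0.17 with an estimated correlation), among them Pik3r1 (4.23 ± 0.40), Fkbp5 (4.00 ± 0.47) and Foxo1 (3.53 ± 0.57). STAT3 and acute phase genes rose in 14 of 23 cases (20 adjusted over the list alone; adjusted p = 3.1e-09, adjusted p = 0.25 with an estimated correlation), among them Lcn2 (5.62 ± 0.75), Il6ra (5.06 ± 0.54) and Cebpd (4.63 ± 0.43). Ubiquitin ligase genes of atrophy rose in 16 of 26 cases (16 adjusted over the list alone; adjusted p = 5.5e-06, adjusted p = 0.25 with an estimated correlation), including Siah1a (2.48 ± 0.25). Proteasome genes rose in 24 of 33 cases (28 adjusted over the list alone; adjusted p = 1.1e-09, adjusted p = 0.51 with an estimated correlation) and ribosomal protein genes in 53 of 59 (58 adjusted over the list alone; adjusted p = 2.0e-14, adjusted p = 0.51 with an estimated correlation). Autophagy and lysosome genes rose in 17 of 34 cases (20 adjusted over the list alone; adjusted p = 7.4e-07, adjusted p = 0.36 with an estimated correlation), including Map1lc3b (1.73 ± 0.17) and Bnip3 (2.10 ± 0.25). Of 36 genes of fatty acid use 14 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 3.5e-04, adjusted p = 0.55 with an estimated correlation), led by Pdk4 (4.26 ± 0.56) and Acot1 (5.04 ± 0.78). Beside these, adipocyte markers rose in 5 of 13 cases and fell in 1 (7 and 1 adjusted over the list alone; median 1.98; adjusted p = 0.018, adjusted p = 0.51 with an estimated correlation). Of these, 2 were called higher without Matrigel_control replicate 1, 1 without Matrigel_control replicate 2, and 3 without KPC_tumor replicate 1, where the list's adjusted p was 0.0551. Neutrophil markers rose in 12 of 13 cases (12 adjusted over the list alone), including S100a9 (5.96 ± 0.50); the list passed with the preset (adjusted p = 6.4e-10) and with an estimated correlation (adjusted p = 0.032), as did antioxidant and metallothionein genes (15 of 22 higher and 1 lower, 16 and 2 adjusted over the list alone; adjusted p = 5.5e-06, adjusted p = 0.032 with an estimated correlation). Erythroid markers had a median of 2.60, with 7 of 10 higher.

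Collagen and matrix genes fell in 22 of 39 cases and rose in 3 (22 and 4 adjusted over the list alone; adjusted p = 2.8e-05, adjusted p = 0.55 with an estimated correlation), among them Col3a1 (-4.70 ± 0.59), Col6a1 (-3.16 ± 0.43) and Col6a3 (-3.43 ± 0.43). Tendon markers fell in 8 of 12 cases (10 adjusted over the list alone; median -3.67; adjusted p = 3.6e-04, adjusted p = 0.51 with an estimated correlation). Interferon-response genes fell in 17 of 29 cases (20 adjusted over the list alone; adjusted p = 3.3e-06, adjusted p = 0.39 with an estimated correlation), among them Oasl2 (-2.28 ± 0.37), Gbp5 (-2.63 ± 0.43) and Irf1 (-1.64 ± 0.28). Oxidative phosphorylation genes had a median of -0.37 with 7 of 51 lower (1 adjusted over the list alone; adjusted p = 0.0019, adjusted p = 0.76 with an estimated correlation). The list's adjusted p was 0.237 without Matrigel_control replicate 2. The number of ribosomal protein genes called higher was 7 without Matrigel_control replicate 1, 9 without KPC_tumor replicate 1 and 19 without Matrigel_control replicate 2.

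In total 4674 genes passed, 2465 higher and 2209 lower, and 18 lists passed camera with the preset correlation against 2 with an estimated correlation. The larger number was that of lower genes with a fold threshold of 2 (1315 higher and 1503 lower) and without Matrigel_control replicate 2 (1013 and 1020). The count of genes was 2667 without Matrigel_control replicate 1, 2033 without Matrigel_control replicate 2 and 2514 without KPC_tumor replicate 2. With only the libraries of the KPC and Matrigel groups it was 2587. By fry, the oxidative phosphorylation list did not pass (adjusted p = 0.2). Without Matrigel_control replicate 1, 13 proteasome genes and 9 genes of fatty acid use were called higher, and 11 interferon-response genes, 11 collagen genes and 3 tendon markers lower. Without Matrigel_control replicate 2, 9 proteasome genes, 8 ubiquitin ligases, 8 autophagy genes, 7 neutrophil markers and 7 antioxidant genes were called higher, and 10 interferon-response genes lower. Without KPC_tumor replicate 1, 13 collagen genes were called lower. Without KPC_tumor replicate 2, 8 ubiquitin ligases and 8 genes of fatty acid use were called higher, and 10 interferon-response genes and 4 tendon markers lower.

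KPC and KPCML1 tumour groups were then compared directly, which the common controls do not enter; they differed in line and in number of cells injected, so these cannot be told apart. In the KPC group 473 genes were higher and 491 lower. This balance turned to 513 higher and 454 lower with size factors by relative log expression, 1053 and 667 with DESeq2 and 357 and 273 with length-scaled counts. It was 1133 and 850 with no filter on low counts, and 11 and 3 with the libraries of these tumour groups alone. The largest increases were in Adamtsl2 (5.72 ± 1.00), Tmem82 (4.56 ± 0.93), Ampd3, an AMP deaminase (4.50 ± 0.78), Htra1, a secreted protease (4.07 ± 0.61), Adamts2, a procollagen protease (3.96 ± 0.91), and Greb1 (3.94 ± 0.98). The largest decreases were in Sox18, a transcription factor of endothelial cells (-3.13 ± 0.45), Amd1 (-2.96 ± 0.44), the interferon-inducible GTPase genes Gbp4 (-2.52 ± 0.48) and Iigp1 (-2.36 ± 0.58), Plcd4 (-2.47 ± 0.64) and the nuclear RNA Neat1 (-2.45 ± 0.52). Interferon-response genes lay 1.19 higher (median log2) in KPCML1 than in KPC. For these genes camera gave adjusted p = 1.7e-12, and adjusted p = 0.37 with an estimated correlation. Ubiquitin ligase genes lay lower in KPCML1 by a median of -0.49 (adjusted p = 2.2e-04, and adjusted p = 0.54 with an estimated correlation).

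The total of 964 genes rested on few libraries: it was 21 without KPCML1_tumor replicate 1, 86 without KPCML1_tumor replicate 2, 103 without KPC_tumor replicate 2 and 2033 without KPC_tumor replicate 1. Of the 12 genes named, Sox18 alone was called in all 4 of these fits and the other 11 lost their call without KPCML1_tumor replicate 1. Amd1 (adjusted p 0.0626) and Htra1 (0.0794) lost it in that fit only. Adamtsl2 (0.0636 to 0.107) also lost it without KPCML1_tumor replicate 2, and Gbp4 (0.101 to 0.11) without KPC_tumor replicate 2. Ampd3 (0.0695 to 0.103), Tmem82 (0.1 to 0.235), Adamts2 (0.132 to 0.535), Greb1 (0.13 to 0.628), Neat1 (0.0611 to 0.149) and Iigp1 (0.0537 to 0.236) lost it without either of these. Plcd4 (0.0515 to 0.346) also lost it without either KPC_tumor replicate. With the replicate block 241 genes passed, and with the libraries of these tumour groups alone 14.

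The KPC and KPCML1 effects shared a direction in 1103 called genes, 561 higher and 542 lower, where lists drawn independently would share 102.3 and 96.8. Their log2 fold changes correlated across genes at r = 0.649. As both use the same 2 controls, 20 simulations with shared controls and no tumour effect were run. They gave a mean r of 0.495, at most 0.527. The covariance was 0.86 against a simulated 0.176. Unshared effects were not simulated.

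The C26 comparison asked how muscle of CD2F1 mice with C26 tumours differed from that of PBS-injected mice. Called higher were 20 of 23 STAT3 and acute phase genes, and called lower 31 of 51 oxidative phosphorylation, 16 of 29 glycolysis, 9 of 18 fast myofibre and 6 of 12 tendon genes. All 5 lists passed camera with the preset correlation and none with an estimated correlation (adjusted p 0.16 to 0.38). Mt2 rose from 2.40 ± 0.376 to 1100 ± 540 CPM (SD, n = 2; 8.84 ± 1.07) and Mt1 from 8.52 ± 1.05 to 982 ± 639 CPM (6.85 ± 0.78). Lcn2, an iron-siderophore-binding acute phase protein on chromosome 2 (32384633 to 32388252), rose from 0.505 ± 0.0517 to 82.1 ± 43.3 CPM (7.33 ± 0.80). Fbxo32 rose from 169 ± 19.7 to 1500 ± 366 CPM (3.15 ± 0.35) and Trim63 from 188 ± 8.27 to 1820 ± 887 CPM (3.28 ± 0.47).

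Serpina3n (7.02 ± 0.92), a serine protease inhibitor, and the chemokine gene Cxcl13 (6.90 ± 0.55) also rose, and its near-identical relative Serpina3m, with 1 count over both controls, had a ratio of 629 (95% counting interval 113 to 24900). The largest decreases were in Chad (-6.15 ± 1.31), Irx3os (-6.06 ± 0.60), the methyltransferase gene Mettl21c (-5.77 ± 0.70), Nnat (-5.54 ± 0.88), Mdga1 (-5.45 ± 0.65) and the small proteoglycan gene Kera (-5.22 ± 1.15). Of these 12 genes, 10 were called with each of the 4 libraries left out in turn; Chad and Kera lost their call without C26_tumor replicate 2 (adjusted p 0.0665 and 0.0689).

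STAT3 and acute phase genes rose in 20 of 23 cases (20 adjusted over the list alone; adjusted p = 1.2e-11, adjusted p = 0.16 with an estimated correlation), including Stat3 (1.87 ± 0.37) and Il4ra (2.36 ± 0.27). NF-kB targets rose in 9 of 24 cases (13 adjusted over the list alone; adjusted p = 1.6e-05, adjusted p = 0.16 with an estimated correlation), among them Nfkb2 (2.82 ± 0.28) and Birc3 (1.83 ± 0.28). Ribosomal protein genes rose in 56 of 59 cases (58 adjusted over the list alone; adjusted p = 1.4e-21, adjusted p = 0.38 with an estimated correlation), among them Rpl10a (1.32 ± 0.17). Proteasome genes rose in 17 of 33 cases (23 adjusted over the list alone; adjusted p = 7.3e-08, adjusted p = 0.43 with an estimated correlation) and autophagy and lysosome genes in 16 of 34 (17 adjusted over the list alone; adjusted p = 6.0e-06, adjusted p = 0.38 with an estimated correlation), among them Ctsl (2.58 ± 0.35). Neutrophil markers rose in 5 of 13 cases (8 adjusted over the list alone; adjusted p = 1.8e-05, adjusted p = 0.16 with an estimated correlation), while erythroid markers had a median of -0.49 with 1 of 10 lower. Chrna1, a subunit of the muscle acetylcholine receptor, rose (3.06 ± 0.58) and Ache, which encodes acetylcholinesterase, fell (-2.30 ± 0.32).

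Oxidative phosphorylation genes fell in 31 of 51 cases (44 adjusted over the list alone; adjusted p = 1.1e-14, adjusted p = 0.38 with an estimated correlation), including Uqcrc1 (-1.44 ± 0.21) and Cox7a1 (-2.26 ± 0.42). Citric acid cycle genes fell in 14 of 19 cases and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 1.3e-07, adjusted p = 0.38 with an estimated correlation), and glycolysis and glycogen genes fell in 16 of 29 and rose in 2 (16 and 2 adjusted over the list alone; adjusted p = 5.5e-07, adjusted p = 0.33 with an estimated correlation), including Pkm (-1.73 ± 0.21) and Tpi1 (-2.07 ± 0.27). Fast myofibre genes fell in 9 of 18 cases (9 lower and 1 higher adjusted over the list alone; adjusted p = 1.1e-04, adjusted p = 0.38 with an estimated correlation), led by the calcium-storage protein gene Casq1 (-3.44 ± 0.30) and Myl1 (-2.52 ± 0.35). Myh4, Myh2 and Myh1 did not pass (0.09 ± 0.42, 0.17 ± 0.59 and 0.62 ± 0.32), and the Myh4 value turned to -1.04 without C26_tumor replicate 1. Tendon markers fell in 6 of 12 cases and rose in 1 (8 and 1 adjusted over the list alone; median -2.61; adjusted p = 2.0e-05, adjusted p = 0.38 with an estimated correlation). Adipocyte markers had a median of -2.02, with 6 of 13 lower and 1 higher (8 and 2 adjusted over the list alone; adjusted p = 0.019, adjusted p = 0.38 with an estimated correlation), and without C26_tumor replicate 2 the adjusted p was 0.0742. Beside that fall, the summed CPM of 18 epidermal genes was 89.5 and 159 in the C26 controls and 21.8 and 20.1 in the tumour libraries.

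In total 3419 genes passed, 1843 higher and 1576 lower, and 19 lists passed camera with the preset correlation against 0 with an estimated correlation. The balance turned to 1613 higher and 1717 lower with size factors by relative log expression, 1830 and 1889 with DESeq2, 1403 and 1425 with length-scaled counts, 1927 and 1979 with no filter, 941 and 980 with a fold threshold of 2, and 1504 and 1554 with the libraries of this experiment alone. It was 716 and 771 without C26_control replicate 1, and 698 and 748 without C26_control replicate 2. The count of genes was 1487 without C26_control replicate 1, 1446 without C26_control replicate 2 and 1093 without C26_tumor replicate 2. In C26_tumor replicate 2 the 10 most abundant genes held 13.1% of the fragments, the lowest share of the 18 libraries. Without C26_control replicate 1, 7 proteasome genes, 13 STAT3 genes, 5 NF-kB targets and 13 ribosomal protein genes were called higher, and 15 oxidative phosphorylation genes and 9 citric acid cycle genes lower. Without C26_control replicate 2, 5 proteasome genes, 12 STAT3 genes, 4 NF-kB targets and 9 autophagy genes were called higher, and 13 oxidative phosphorylation genes lower. Without C26_tumor replicate 1, 10 tendon markers were called lower. Without C26_tumor replicate 2, 5 proteasome genes, 13 STAT3 genes, 4 NF-kB targets, 24 ribosomal protein genes and 8 autophagy genes were called higher, and 9 oxidative phosphorylation genes, 6 citric acid cycle genes and 1 tendon marker lower.

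The KPP comparison asked how muscle of tumour-bearing KPP mice differed from that of KPP mice without tumour. Called higher were 59 of 59 ribosomal protein and 29 of 33 proteasome genes, and called lower 30 of 39 collagen and matrix genes and 16 of 19 endothelial, 10 of 13 pericyte and 14 of 20 fibro-adipogenic progenitor markers. All 6 lists passed camera with the preset correlation and none with an estimated correlation (adjusted p 0.29 to 0.36). Trim63 rose from 312 ± 142 to 2680 ± 250 CPM (SD, n = 2; 3.10 ± 0.47) and Fbxo32 from 337 ± 106 to 1240 ± 199 CPM (1.88 ± 0.33). Col3a1, a fibrillar collagen gene, fell (-5.30 ± 0.61), as did Col1a1 (-4.66 ± 0.83).

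The largest increases were in Chrna9, an acetylcholine receptor subunit gene that averaged 31.9 ± 41.2 CPM in the tumour libraries (7.91 ± 1.76), S100a8 (6.31 ± 1.03), Cdhr3 (6.11 ± 0.79), Lcn2 (5.38 ± 0.74) and Sln, which encodes sarcolipin, a regulator of the calcium pump (5.15 ± 0.87). Chil3, with 3 counts over both controls, had a ratio of 265 (95% counting interval 90.3 to 1290). The largest decreases were in genes of the epidermis. Krtdap, Lce1m, Calm4 and Fam25c had 0 counts in both tumour libraries and were at least 269-fold, 237-fold, 198-fold and 124-fold lower there, taking a floor of 3 counts over the group. Krt77 and Dmkn had 1 count in the tumour libraries and ratios of 0.00034 (95% counting interval 9e-06 to 0.0019) and 0.000519 (1.3e-05 to 0.00289). These transcripts lay chiefly in KPP_control replicate 1: Krt77 was at 87.6 CPM in that library and at 0.0999 CPM in KPP_control replicate 2. Of the 12 genes, 7 were called with each of the 4 libraries left out in turn. Without KPP_control replicate 1 the adjusted p was 0.106 for Krtdap, 0.337 for Fam25c and 0.33 for Dmkn; Krt77 (0.0672 to 0.686) and Lce1m (0.0736 to 0.425) lost their call without this library or either tumour library.

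All 59 ribosomal protein genes rose (59 adjusted over the list alone; adjusted p = 1.7e-29, adjusted p = 0.29 with an estimated correlation), among them Rpl10a (1.84 ± 0.17) and Rps28 (1.91 ± 0.21). Proteasome genes rose in 29 of 33 cases and fell in 1 (30 and 1 adjusted over the list alone; adjusted p = 1.4e-11, adjusted p = 0.36 with an estimated correlation), including Psmd4 (2.39 ± 0.28). Glucocorticoid and FoxO targets rose in 19 of 28 cases and fell in 1 (19 and 1 adjusted over the list alone; adjusted p = 4.2e-07, adjusted p = 0.29 with an estimated correlation), among them Eif4ebp1 (3.96 ± 0.36) and Klf15 (2.18 ± 0.26). Autophagy and lysosome genes rose in 19 of 34 cases and fell in 2 (21 and 2 adjusted over the list alone; adjusted p = 5.4e-07, adjusted p = 0.29 with an estimated correlation). Neutrophil markers rose in 8 of 13 cases (9 higher and 1 lower adjusted over the list alone; adjusted p = 8.5e-04, adjusted p = 0.29 with an estimated correlation), beside an erythroid median of 0.89 with 1 of 10 lower. Runx1 (3.13 ± 0.62), a gene induced by denervation, rose in the neuromuscular list, which had 7 of 25 higher and 5 lower (7 and 5 adjusted over the list alone) and did not pass camera (adjusted p = 0.79, and adjusted p = 0.93 with an estimated correlation). Of that list 2 were called lower without KPP_control replicate 1 and 3 without KPP_tumor replicate 1, and 4 higher without KPP_tumor replicate 2. Myh1 rose (1.93 ± 0.33) in the fast myofibre list, in which 8 of 18 fell and 2 rose (8 and 2 adjusted over the list alone; median -0.73; adjusted p = 0.022, adjusted p = 0.54 with an estimated correlation). The fast myofibre list had an adjusted p of 0.147 without KPP_control replicate 2 and of 0.0809 without KPP_tumor replicate 2, and 1 of its genes was called higher without KPP_control replicate 1 or KPP_tumor replicate 1.

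Endothelial markers fell in 16 of 19 cases (17 adjusted over the list alone; adjusted p = 4.2e-07, adjusted p = 0.29 with an estimated correlation), among them Tek (-1.86 ± 0.23), Tie1 (-2.20 ± 0.34) and Eng (-2.04 ± 0.29). Pericyte and smooth muscle markers fell in 10 of 13 cases (10 adjusted over the list alone; adjusted p = 8.5e-04, adjusted p = 0.29 with an estimated correlation), including Cspg4 (-2.97 ± 0.38) and Notch3 (-2.17 ± 0.47). Fibro-adipogenic progenitor markers fell in 14 of 20 cases (14 lower and 1 higher adjusted over the list alone; adjusted p = 6.9e-06, adjusted p = 0.29 with an estimated correlation), including Dpt (-2.82 ± 0.37) and Smoc2 (-1.64 ± 0.21). Collagen and matrix genes fell in 30 of 39 cases and rose in 1 (30 and 1 adjusted over the list alone; adjusted p = 6.1e-10, adjusted p = 0.29 with an estimated correlation), including Col6a2 (-4.29 ± 0.56) and Sparc (-2.35 ± 0.30). Tendon markers fell in 9 of 12 cases and rose in 1 (10 and 1 adjusted over the list alone; median -3.89; adjusted p = 0.0017, adjusted p = 0.39 with an estimated correlation), and 5 were called lower without KPP_control replicate 1. The Schwann cell gene Sox10 (-2.97 ± 0.58) fell in a list with 5 of 13 lower (5 adjusted over the list alone; adjusted p = 0.0066, adjusted p = 0.39 with an estimated correlation), whose adjusted p was 0.0607 without KPP_control replicate 2. Interferon-response genes fell in 17 of 29 cases (20 adjusted over the list alone; adjusted p = 1.1e-05, adjusted p = 0.29 with an estimated correlation); 4 did so without KPP_control replicate 1. Adipocyte markers fell in 10 of 13 cases and rose in 1 (10 and 1 adjusted over the list alone; median -2.35; adjusted p = 0.0026, adjusted p = 0.29 with an estimated correlation), with 6 lower without KPP_control replicate 1 or without either tumour library. Beside these falls, the summed CPM of 18 epidermal genes was 629 and 16.9 in the KPP controls and 16.7 and 157 in the tumour libraries, where Krt14 held 66.6 of the 157 CPM.

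In total 5909 genes passed, 2804 higher and 3105 lower, and 23 lists passed camera with the preset correlation against 0 with an estimated correlation. This balance turned to 3021 higher and 2889 lower with size factors by relative log expression, 3039 and 2770 with DESeq2, 2662 and 2507 with length-scaled counts, 3103 and 3043 with no filter, and 1799 and 1633 with the libraries of this experiment alone. It was 2364 and 2285 without KPP_tumor replicate 1, and 2660 and 2215 without KPP_tumor replicate 2. The count of genes was 3238 without KPP_control replicate 1. With the libraries of this experiment alone it was 3432, and with a fold threshold of 2 it was 3860. Without KPP_control replicate 1, 19 proteasome genes and 5 neutrophil markers were called higher. Without KPP_control replicate 2, 5 neutrophil markers were called higher. Without KPP_tumor replicate 1, 3 Schwann cell markers were called lower. Without KPP_tumor replicate 2, 4 neutrophil markers were called higher, and 3 Schwann cell markers lower.

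**Figure D2:**
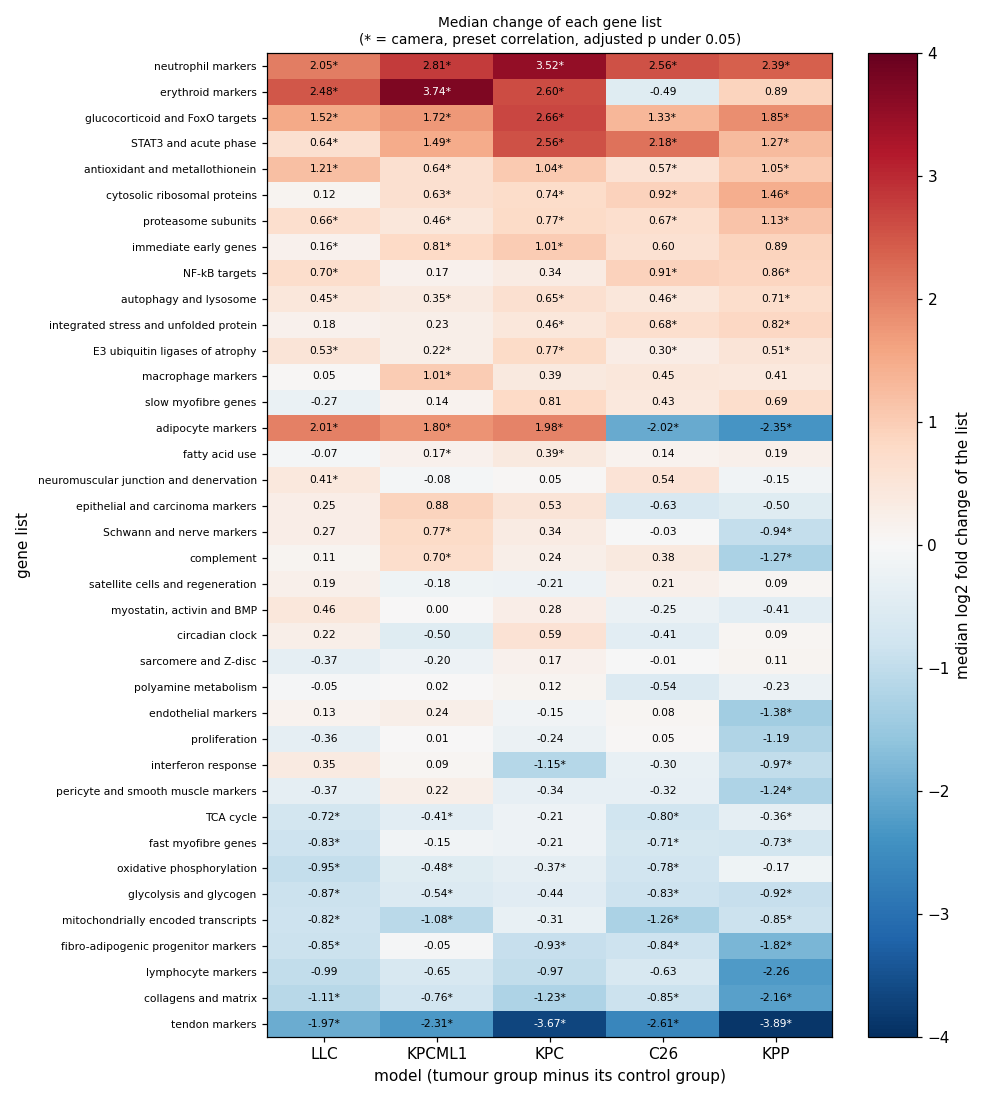
Median log2 fold change, tumour minus control, of each of the 38 gene lists (vertical axis) in the 5 models (horizontal axis), with a star where camera with the preset correlation gave an adjusted p under 0.05. Neutrophil markers were starred in all 5 models (2.05 to 3.52), and endothelial markers in KPP alone (-1.38). With an estimated correlation the neutrophil list passed in KPCML1 and KPC and not in LLC (adjusted p = 0.24), C26 (0.16) and KPP (0.29), and the endothelial list did not pass in KPP (0.29).

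Across models, 462 genes changed in the same direction in all 5 comparisons, 213 higher and 249 lower, where independent lists would share 0.15 and 0.11. These expected numbers do not allow for the controls that KPC and KPCML1 share. Of the 10 common genes ranked by their smallest absolute change, those that rose included Depp1 (3.92 to 4.64), Tmem252 (3.55 to 6.07), Cxcl13 (up to 6.90, and in LLC, with 2 counts over both controls, a ratio of 9.63 with an interval of 2.34 to 85), Mt2 (3.12 to 8.84) and Cdkn1a (3.10 to 6.26). Common decreases were in Irx3os (absolute log2 fold changes 4.85 to 6.47, and in KPP, with 3 counts in the tumour libraries, a ratio of 0.0192 with an interval of 0.0039 to 0.0573), Nrep (3.92 to 5.34), Mettl21c (3.28 to 5.77) and the potassium channel gene Kcng4 (3.26 to 6.13). Clec4e, a lectin of myeloid cells, was higher in each model and had 0 counts in 3 of the control groups, where it was at least 5.1-fold (LLC), 3.23-fold (C26) and 6.37-fold (KPP) higher; against the Matrigel controls, with 1 count, its ratio was 21.6 (3.48 to 895) in KPCML1 and 23.7 (3.86 to 974) in KPC. Leaving out a library ended some calls (adjusted p in parentheses). In LLC, the call of Clec4e (0.107 to 0.122), Cxcl13 (0.121 to 0.128) and Mt2 (0.0688 to 0.425) ended without LLC_control replicate 1, LLC_control replicate 2 or LLC_tumor replicate 2. That of Cdkn1a in LLC (0.0512) ended without LLC_control replicate 1. In KPCML1, the call of Clec4e (0.0542 to 0.242) ended without any of the 4 libraries and that of Mettl21c (0.0812) without KPCML1_tumor replicate 2. That of Mt2 in KPCML1 (0.119 to 0.317) ended without either Matrigel control or KPCML1_tumor replicate 2, and that of Cdkn1a (0.0512 to 0.0759) without Matrigel_control replicate 2 or KPCML1_tumor replicate 2. In KPC, the call of Clec4e (0.0623 to 0.0936) ended without Matrigel_control replicate 2 or KPC_tumor replicate 2. In C26, the call of Clec4e (0.125 to 0.147) ended without C26_control replicate 1, C26_control replicate 2 or C26_tumor replicate 2. All 10 kept their call in KPP. The count of common genes fell to 89 without KPCML1_tumor replicate 2, 107 without Matrigel_control replicate 2, 203 and 255 without LLC_control replicates 1 and 2, 219 without LLC_tumor replicate 2, 230 without Matrigel_control replicate 1 and 294 without C26_control replicate 2. It was 243 with a fold threshold of 2, 255 with the replicate block and 748 with no filter on low counts.

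The size of the change differed among the 5 models in 1339 genes. Among those with the smallest p were Ushbp1, which fell in KPC (-1.84 ± 0.20) and KPP (-2.41 ± 0.20) and had values of -0.44 ± 0.19 in LLC, -0.03 ± 0.19 in KPCML1 and -0.14 ± 0.19 in C26, and the endothelial transcription factor gene Sox7, which fell in KPCML1 (-1.10 ± 0.26), C26 (-1.45 ± 0.27), KPC (-2.54 ± 0.28) and KPP (-3.14 ± 0.30) and had a value of 0.22 ± 0.26 in LLC. Nfkb2 rose in LLC (3.86 ± 0.29), C26 (2.82 ± 0.28) and KPP (1.57 ± 0.27) and had values of 0.16 ± 0.27 in KPCML1 and 0.15 ± 0.27 in KPC. Dbp fell in KPCML1 (-2.86 ± 0.32), C26 (-3.47 ± 0.33), KPP (-4.24 ± 0.35) and KPC (-4.78 ± 0.35) and had a value of 0.19 ± 0.30 in LLC. Agt, which encodes angiotensinogen, fell in LLC (-3.11 ± 0.33), rose in KPC (1.61 ± 0.29) and KPP (1.24 ± 0.29). Dhrs7c fell in LLC (-2.77 ± 0.22), C26 (-1.27 ± 0.21) and KPP (-0.58 ± 0.21). Fmo1 rose in KPCML1 (0.62 ± 0.17), fell in C26 (-0.56 ± 0.17), KPC (-0.69 ± 0.17) and KPP (-1.68 ± 0.17). Adh1 rose in LLC (0.92 ± 0.19), fell in KPC (-0.88 ± 0.19) and KPP (-1.20 ± 0.19). Tmcc3 rose in KPCML1 (0.67 ± 0.16), KPP (0.99 ± 0.16) and KPC (2.02 ± 0.17). Trim47 fell in KPC (-2.32 ± 0.23) and KPP (-1.65 ± 0.23). In models not given for a gene here, it was not called. With 1 library left out some calls ended (adjusted p in parentheses): in KPCML1 those of Sox7 (0.085 to 0.148) and Fmo1 (0.0989 to 0.198) without any of the 4 libraries, and that of Tmcc3 (0.0701 to 0.242) without Matrigel_control replicate 2 or either KPCML1_tumor replicate. In KPC those of Fmo1 (0.0503 to 0.0695) without Matrigel_control replicate 2 or KPC_tumor replicate 1 and of Adh1 (0.0557) without Matrigel_control replicate 2 ended. Fmo1 in C26 (0.0989 to 0.232) lost its call without either C26_control replicate or C26_tumor replicate 2, and Adh1 in LLC (0.0516 to 0.1) without LLC_control replicate 1 or LLC_tumor replicate 1. In KPP, Agt lost it without KPP_control replicate 1 (0.0688) and Dhrs7c without any of the 4 (0.0691 to 0.215). The count of 1339 moved to 2716 without KPC_tumor replicate 1, to 457 and 498 without LLC_control replicates 1 and 2, to 563 and 655 without LLC_tumor replicates 2 and 1, to 626 without either Matrigel control, to 537 and 635 without KPCML1_tumor replicates 1 and 2, to 539 and 567 without C26_control replicates 1 and 2, and to 618 without KPP_control replicate 1. With the replicate block it was 285, with length-scaled counts 879, with DESeq2 3363 and with no filter on low counts 4128.

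The tables of results that the authors deposited, made with DESeq2, held 24569 genes each. They called 3167 genes in LLC, 3026 in C26, 3165 in KPP, 2930 in the table named 50K and 2108 in the table named 10K. Of the genes called in both sources, 1843 of 1843 had the same direction in LLC, 2421 of 2421 in C26, 2933 of 2934 in KPP and 2635 of 2637 for 50K against KPC. The log2 fold changes of the 10K table correlated across genes at r = 0.903 with KPCML1 and at 0.658 with KPC, although the labels give 1000 cells for KPCML1.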

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

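Of the tests of explanations, those of KPP_control replicate 1 alone and of the scaling of the libraries in the KPP marker lists were written before their results were seen; the tests of skin in KPP_control replicate 1, of skin in several control libraries, of a fall against both controls, of blood in each model, with and without Bpgm and Fech, and of a lower share of every cell type other than myofibres were chosen only after the results were seen.

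Genes of the epidermis were lower in the KPP tumour group. Of 24 epidermal genes, 6 named and 18 listed, 18 were called lower and 1, Trp63, higher. The 18 lower genes had a median CPM of 26.3 in KPP_control replicate 1 and 0.0999 in replicate 2. Picked as lower and there under the 1 CPM floor, they cannot test a fall against both controls. The 18 listed genes summed to 629 CPM in KPP_control replicate 1, 16.9 in replicate 2 and 16.7 and 157 in the tumour libraries. The sum thus fell only against replicate 1. The median log2 ratio of replicate 1 to the highest other library was 1.97, under the 3 set for skin there alone. The C26 controls held 89.5 and 159 CPM. Skin in several control libraries is a candidate, as the log2 ratio of replicate 1 to C26_control replicate 2 had an SD of 0.49. Whether this was skin stays open.

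Neutrophil markers were higher in all 5 tumour groups by camera with the preset correlation, and with an estimated correlation in KPCML1 (adjusted p = 0.029) and KPC (0.032) but not in LLC (adjusted p = 0.24), C26 (0.16) and KPP (0.29). In C26 their mean log2 change exceeded that of erythroid markers by 2.22 (SE 0.57), and by 2.08 (SE 0.55) without Bpgm and Fech, 2 of the 10 erythroid genes that other tissues also express, which argues against more blood left in the muscle. In KPP the same difference was 1.46 (SE 1.33), in LLC -0.71 (SE 0.64), in KPCML1 -0.57 (SE 0.25) and in KPC 0.95 (SE 0.24), or without these 2 genes 1.19 (SE 1.58), -1.32 (SE 0.80), -1.35 (SE 0.32) and 0.30 (SE 0.25), and in the last 3 erythroid markers were higher too, by 1.84, 2.87 and 2.30 over all 10, so more blood and more neutrophils in muscle cannot be told apart in these 4 models. The mean of the lymphocyte markers changed by -0.92 in LLC, -0.92 in KPCML1, -1.68 in KPC, -1.64 in C26 and -2.58 in KPP, where more blood of the same composition would raise it, but of the 3 such genes tested Cd2 and Cd79b reached at most 0.531 and 0.549 CPM, and Ighm alone, at up to 67.1 CPM, was called lower in each model (-1.59 in LLC, -3.23 in KPCML1, -4.39 in KPC, -4.97 in C26 and -5.06 in KPP), in LLC not without LLC_control replicate 2 or either LLC_tumor replicate (adjusted p 0.0895 to 0.404) and in KPCML1 not without KPCML1_tumor replicate 2 (0.0641); that goes against more blood of the same composition, but is 1 gene. A changed composition of the blood, reticulocytes included, stays open in all 5 models.

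Endothelial, pericyte and fibro-adipogenic markers were lower in the KPP tumour group by camera with the preset correlation, but each list had adjusted p = 0.29 with an estimated correlation. The highest of the 3 list medians was -1.1 without KPP_control replicate 1, which argues against that library as the whole cause. It was -1.2 by relative log expression, but both scalings assume mostly unchanged genes, so scaling stays open. The change in macrophage markers (0.19) exceeded that in endothelial markers (-1.5) by 1.69 on the log2 scale (SE 0.46), which argues against a lower share of every cell type other than myofibres. Fewer such cells or less of these transcripts per cell are hypotheses not separated.

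The change differed among the 5 models in 1339 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In pairs, LLC differed from KPCML1 in 29 genes, KPC in 296, C26 in 75 and KPP in 1333. KPCML1 differed from KPC in 964, C26 in 3 and KPP in 559. KPC differed from C26 in 140 and KPP in 6, and C26 from KPP in 174. Shared controls of KPC and KPCML1 cancel, so 964 cannot be ranked with the other counts, whose pairs also differ in experiment.

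Named genes whose change differed among models had these ranges of their 5 log2 fold changes: 9.29 for Slc15a2, 8.56 for Ces2c, 8.26 for Lcn2, 7.37 for Cdhr3, 7.02 for Nnat, 6.98 for Slc4a1, 6.71 for Serpina3n, 6.29 for Ggt6, 5.79 for BB123696, 5.75 for Adamtsl2 and 5.71 for Mt2. Next came 5.0 for Mt1, 4.98 for Dbp, 4.82 for Greb1, 4.72 for Agt, 4.61 for Htra1, 4.56 for Tmem82, 4.51 for Sesn1, 4.5 for Ampd3, 4.21 for Adamts2, 4.21 for Col9a1, 4.08 for Pdk4 and 3.71 for Nfkb2. Ranges further down were 3.7 for Arntl, 3.54 for Neat1, 3.54 for Sox10, 3.47 for Ighm, 3.45 for S100a9, 3.43 for Amd1, 3.35 for Sox7, 3.34 for Pik3r1, 3.28 for Gbp5, 3.23 for Gbp4, 3.21 for Sox18 and 3.16 for Cdkn1a. Then followed 3.12 for Relb, 2.96 for Col3a1, 2.9 for Plcd4, 2.87 for Kcng4, 2.86 for Dhrs7c, 2.85 for Oasl2, 2.66 for Paox, 2.61 for Fkbp5, 2.52 for Per2, 2.52 for Tmem252, 2.47 for Cspg4 and 2.46 for Gadd45a. Among smaller ranges were 2.42 for Eif4ebp1, 2.38 for Ushbp1, 2.33 for Eng, 2.32 for Hlf, 2.32 for Tie1, 2.3 for Fmo1, 2.3 for Trim47, 2.24 for Mstn, 2.23 for Col6a3, 2.19 for Hdac4, 2.16 for Cebpd and 2.16 for Tek. After these came 2.12 for Adh1, 2.1 for Myh1, 2.07 for Casq1, 2.03 for Srxn1, 2.03 for Tmcc3, 1.99 for Irf1, 1.93 for Jun, 1.85 for Odc1, 1.8 for Rps28, 1.76 for Nqo1, 1.7 for Siah1a and 1.48 for Rpl10a. Still smaller were 1.37 for Bnip3 and 0.7 for Map1lc3b.

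By camera with the preset correlation, the number of the 10 pairs of models that differed was 9 for cytosolic ribosomal proteins, 8 for interferon response, 7 for STAT3 and acute phase, fibro-adipogenic progenitor markers, oxidative phosphorylation and proteasome subunits, 6 for Schwann and nerve markers, TCA cycle, adipocyte markers, erythroid markers and neutrophil markers. It was 5 for NF-kB targets, collagens and matrix, complement, fast myofibre genes, fatty acid use, glycolysis and glycogen, mitochondrially encoded transcripts, myostatin, activin and BMP, pericyte and smooth muscle markers and sarcomere and Z-disc, 4 for E3 ubiquitin ligases of atrophy, autophagy and lysosome, circadian clock, endothelial markers, glucocorticoid and FoxO targets and macrophage markers. It was 3 for satellite cells and regeneration, 2 for antioxidant and metallothionein, neuromuscular junction and denervation and slow myofibre genes, 1 for immediate early genes, integrated stress and unfolded protein, proliferation and tendon markers. With an estimated correlation 0 of the 380 differences passed. Of the largest difference of each list, the smallest p was that of ribosomal protein genes, -1.35 from LLC minus KPP (adjusted p = 1.2e-33, and adjusted p = 0.5 with an estimated correlation).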

How the results depend on the processing

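Only the crossed block of KPP was chosen after the data were seen; the cause of the changes below was not tested. With size factors by relative log expression no count moved by more than 1.5 times, but the balance of higher and lower genes turned in C26, in KPP and between KPC and KPCML1. With replicate number as a block 1329 genes passed in LLC, 690 in KPCML1, 241 between KPC and KPCML1, 285 among models and 255 in common; a crossed block in KPP gave 5553. A fold threshold of 2 left 1264 in LLC, 850 in KPCML1, 2818 in KPC, 1921 in C26, 3860 in KPP and 243 in common. The libraries of the groups compared alone gave 3935 in LLC, 2587 in KPC, 3432 in KPP and 14 between KPC and KPCML1, of which 5 were shared. No filter gave 2244 in KPCML1, 1983 between KPC and KPCML1, 4128 among models and 748 in common. DESeq2 gave 1720 between KPC and KPCML1 and 3363 among models, and length-scaled counts 630 and 879. With an estimated correlation 0 to 2 lists passed per model. By fry 16 lists passed in LLC, 14 in KPCML1, 19 in KPC, 21 in C26 and 26 in KPP, and 14, 13, 16, 17 and 22 of these passed camera. Leaving out 1 library gave 502 to 1208 genes in LLC, 140 to 889 in KPCML1, 2033 to 4633 in KPC, 1093 to 3429 in C26, 3238 to 4970 in KPP, 21 to 2033 between KPC and KPCML1, 457 to 2716 among models and 89 to 572 in common. The sign turned for Myh4 in C26 (-1.04 to 0.72), for Socs3 (-0.45 to 3.96) and Ppargc1a (-0.72 to 2.81) in KPP, for Myl2 in KPC (-1.12 without KPC_tumor replicate 1, up to 4.61) and for Cdh1 in KPP (-5.38 to 0.1, the latter without KPP_control replicate 1). Of single-gene values with 1 library left out, 2885 kept direction and side of the threshold, 775 fell below it, 17 passed it, 46 moved and 5 reversed. Deviations of same-numbered replicates correlated at -0.17 to 0.09 across genes, which does not show pairing.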

Other observations

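Only Trp63 was chosen here after its values were seen. The polyamine genes moved within their list in opposite directions. Smox, which encodes spermine oxidase, fell in LLC (-2.80 ± 0.34), KPCML1 (-2.57 ± 0.34), KPC (-2.49 ± 0.34), C26 (-3.39 ± 0.35) and KPP (-3.33 ± 0.35), while Paox, a polyamine oxidase gene, rose in KPP (2.64 ± 0.40) and Odc1, which encodes ornithine decarboxylase, in LLC (1.74 ± 0.23). Of 10 tested polyamine genes 4 rose and 4 fell in KPP (4 and 4 adjusted over the list alone), and the list did not pass camera in any of the 5 models (adjusted p 0.33 in C26 to 0.99 in LLC and KPC; 0.47 to 1 with an estimated correlation), while by fry it passed in KPC (adjusted p = 0.036), C26 (0.0059) and KPP (0.032). Its median and mean differed in sign in KPCML1 (0.02 and -0.33) and KPC (0.12 and -0.49).

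The clock genes Per2 and Arntl differed among models. Per2 rose in LLC (1.86 ± 0.40) and Arntl in KPC (3.54 ± 0.44), and Arntl had a value of -0.16 in LLC; the adjusted p of edgeR's quasi-likelihood test among models was 0.0433 for Per2 and 0.00824 for Arntl. The call of Per2 in LLC ended without LLC_control replicate 1, LLC_control replicate 2 or LLC_tumor replicate 2 (adjusted p 0.0569 to 0.0955). The circadian list did not pass camera in any model, with an adjusted p of 0.12 in LLC, 0.2 in KPCML1, 0.44 in KPC, 0.33 in C26 and 0.98 in KPP; by fry it passed in LLC (adjusted p = 0.037), KPCML1 (0.046) and C26 (0.016). The times of day of tissue collection are not given in the sources used here.

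Trp63 rose in LLC (2.96 ± 0.54), KPC (2.46 ± 0.53) and KPP (1.74 ± 0.51). KPP controls held 6.97 and 2.9 CPM. Tumour replicate 1 held 6.4, and only replicate 2, at 26.9, exceeded both controls. In KPCML1 (1.31 ± 0.52) and C26 (1.51 ± 0.52) adjusted p was 0.138 and 0.0541, and the test among models gave 0.23.

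Several lists passed camera in some models only. Complement genes had a median of 0.70 in KPCML1 (adjusted p = 0.009, and adjusted p = 0.5 with an estimated correlation) and -1.27 in KPP (adjusted p = 0.011, and adjusted p = 0.45 with an estimated correlation). Those calls ended without Matrigel_control replicate 2 (adjusted p 0.0675), KPCML1_tumor replicate 1 (0.102) and KPP_control replicate 1 (0.0523). Integrated stress and unfolded protein genes, among them Xbp1 (1.36 ± 0.15 in C26), passed in KPC (adjusted p = 0.013), C26 (0.0024) and KPP (0.0035). In KPC the adjusted p was 0.0702 without Matrigel_control replicate 2 and 0.0618 without KPC_tumor replicate 1, and in C26 it was 0.0582 without C26_tumor replicate 2. Immediate early genes passed in LLC (adjusted p = 0.0073), KPCML1 (0.0017) and KPC (0.0023), and had adjusted p 0.22 in C26 and 0.058 in KPP. With an estimated correlation none of these passed. By fry complement in KPCML1 had adjusted p = 0.12 and immediate early genes in KPP 0.029.

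Lists that did not pass camera in any model were slow myofibre genes (adjusted p 0.13 to 0.71), sarcomere and Z-disc genes (0.054 to 0.79), satellite cell and regeneration genes (0.16 to 0.95), the myostatin, activin and BMP list (0.091 to 0.73), proliferation genes (0.06 to 0.94), lymphocyte markers (3 tested genes; 0.056 to 0.38), and epithelial and carcinoma markers (0.2 to 0.95). By fry those passing were sarcomere genes in LLC (adjusted p = 0.037), the myostatin list in KPC (0.036), satellite cell genes in C26 (0.016), proliferation genes in KPP (0.018), and lymphocyte markers in KPC (0.01), C26 (0.01) and KPP (4.4e-04). For proliferation genes in KPCML1 the median was 0.01 and the mean -0.11, and for fatty acid use in LLC they were -0.07 and 0.1. For slow myofibre genes in C26 the median was 0.43 and the mean -0.01. For neuromuscular genes in KPP the median was -0.15 and the mean 0.51, and the satellite cell list in KPP had 0.09 and -0.15. Epithelial and carcinoma markers in KPP had a median of -0.5 and a mean of -0.85 while camera pointed up.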
